A study of Oryza sativa with 24 samples.

How the data were processed

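Young panicles of rice (Oryza sativa, the indica variety IR64) were profiled by RNA sequencing in wild-type plants and in plants with the tps2, tps3 and tps6 genes edited, which encode class II trehalose phosphate synthases. Panicles were taken at 4 developmental stages, numbered 5 to 8, and 3 biological replicates per genotype and stage were labelled, which gave 24 columns in 8 groups. Per the labels' protocols, RNA was extracted with TRIzol and read pairs were sequenced on a NovaSeq instrument.

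The deposited values were whole-number counts per gene. Per the series design text, trimmed read pairs were mapped to the IR64 genome with STAR and the authors counted reads per gene with HTSeq-count on a high-confidence IR64 annotation. The submitters' processing notes also list Trimmomatic 0.39 and kallisto, and the role of kallisto is not given in the sources used here. The strand setting, the treatment of reads shared between near-identical genes and the annotation version are not given in the sources used here either, so counts of paralogs and of overlapping or antisense genes are uncertain. The design text mentions conversion to TPM; only the counts were analysed here.

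The table held 36099 gene identifiers, of which 29979 had a count in at least 1 column, and no row lacked a gene identifier. The reference table used for gene names lists 39387 genes of another rice assembly (ASM3414082v1), and 0 of the identifiers matched it. Genes are therefore given by their identifiers, with at most 2 that rose and 2 that fell per comparison. The edited genes were not analysed by name, so the labels were not checked against them. The 6 lists of named genes (86 members) and 28 keyword lists fixed before the data were examined matched 0 genes and gave no test.

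All 276 pairs of columns were compared. In 3 pairs the mutant and wild-type columns held identical values in every row (stage 6 replicate 3, stage 7 replicate 2 and stage 7 replicate 3), whereas the other pairs differed in at least 23573 rows. Each such pair was taken as 1 library whose genotype is unresolved, and these 3 libraries entered no comparison between groups. This left 18 libraries, with 3 per genotype at stages 5 and 8, 2 per genotype at stage 6 and 1 per genotype at stage 7. The design fixed before the data were examined had all 24 columns in the fit. After the identical columns were seen, the 18 libraries became the main fit. The fit of all 24 columns was kept as an alternative, because it enters the same library under both genotypes.

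Total counts of the 18 libraries ranged from 11398861 to 15860931. Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust), with TMM normalization and genes kept by filterByExpr on the 8 groups, which left 25483 genes. One fit of 8 groups shared the estimate of the spread and had 10 residual degrees of freedom. The lone stage 7 libraries were assumed to vary like the other groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the fitted log2 fold change and its F statistic. Values are CPM, counts scaled to the TMM-normalized library size. For a group with a count of 0, a floor of 3 counts over the group set the lower bound of the fold.

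Mutant and wild type were compared at each stage, adjacent stages were compared within each genotype, and an interaction test asked whether the genotype difference changed with stage. The mean of the 4 genotype differences was added as a contrast after the data were examined. Named genes had the largest fitted change each way among called genes whose groups did not overlap and whose higher group had a mean of at least 5 CPM. This rule was fixed before the data were examined, for 3 libraries per group, and was applied to the libraries left.

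Alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, only the libraries compared, a replicate block, a 2-fold minimum and leaving out each library in turn. The procedure was tested on simulated counts with 50 genes changed per fold size. For the stage 5 genotype comparison (24834 genes), 28% of 2-fold, 76% of 4-fold and 92% of 8-fold changes were recovered. For stage 7 (24824 genes) the shares were 4%, 42% and 66%. Simulated genes kept the same spread at every stage, unlike the libraries, so these shares may overstate recovery where the spread was wider. Gene classes were tested with camera and fry of limma 3.58.1.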

Results

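The libraries measured gene expression in young rice panicles through 4 stages of pollen development, in wild-type IR64 plants and in tps2, tps3 and tps6 triple mutants. Stage 5 is the formation of pollen mother cells, stage 6 their meiosis, stage 7 the filling of pollen and stage 8 pollen maturation. The title of the series places the comparison in the context of spikelet fertility. Of the 24 columns, 6 held 3 libraries that stood under both genotypes, and 18 libraries of resolved genotype were compared. Total counts per library ranged from 11398861 to 15860931 in the mutant and from 11562157 to 13094089 in wild type.

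Developmental stage set the main order of the libraries. The first principal component of log2 CPM took 50.9% of the variance and ran from stage 5 to stage 8, and the second took 15.4%. Replicates were closest in the mutant at stage 5, with correlations across genes of 0.976 to 0.98, and farthest apart in the mutant at stage 8, with 0.848 to 0.908. Wild-type replicates at stage 8 correlated at 0.933 to 0.95. The common biological coefficient of variation was 18.5% at stage 5, 27.3% at stage 6 and 41.4% at stage 8.

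**Figure D1:**
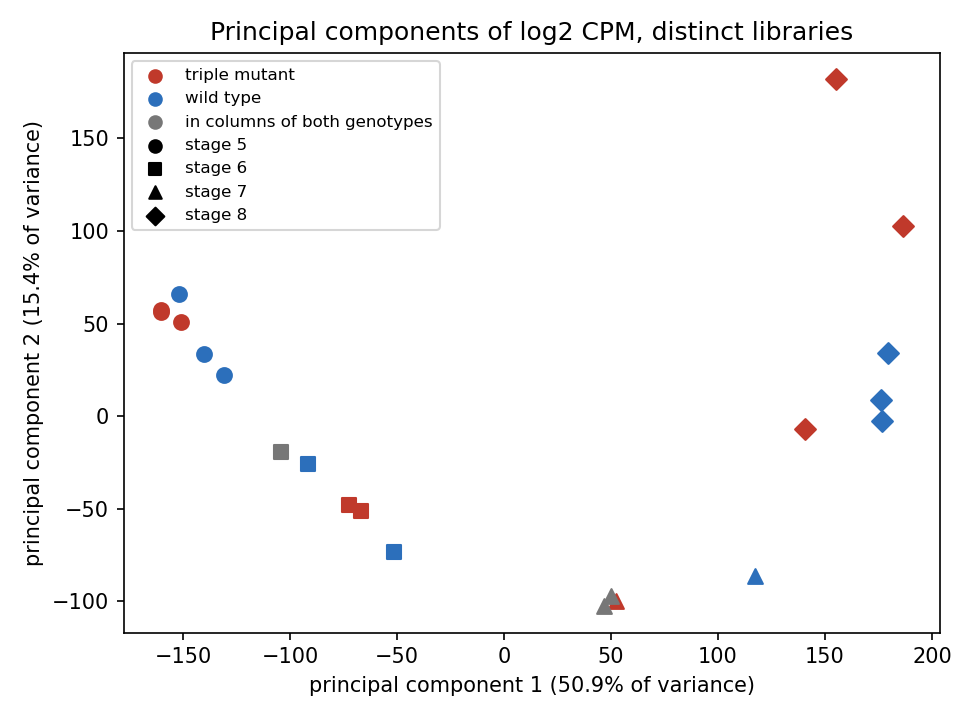
Principal components 1 and 2 of log2 CPM for the 21 distinct libraries, with the share of variance on each axis; colour gives the genotype and shape the stage. Libraries run by stage along component 1, and the 3 mutant stage 8 libraries spread along component 2.

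At stage 5, when pollen mother cells form, no gene passed the threshold between mutant and wild type in edgeR. The unadjusted p was under 0.05 for 1127 of 25483 genes (4.42%), no excess over the share set by that threshold. The median absolute log2 difference was 0.21. DESeq2 called 16 genes, 3 higher and 13 lower in the mutant. A fit of the 6 stage 5 libraries alone called 7 genes, and leaving out wild-type replicate 1 gave 11.

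At stage 6, at meiosis, no gene passed the threshold between the genotypes in edgeR, with 2 libraries per genotype. The unadjusted p was under 0.05 for 755 genes (2.96%), no excess over the share set by that threshold. DESeq2 called 6 genes. Mutant and wild-type libraries correlated with each other at 0.963 to 0.969, against 0.974 within the mutant and 0.954 within wild type.

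At stage 7, when pollen fills, OsIR64_07g0000620 was lower in the mutant, at 14 CPM against 90.7 CPM in wild type (log2 fold change -2.69, SE 0.37, edgeR adjusted p = 0.031). It was the 1 gene called. With 1 library per genotype the comparison has no replicate at this stage and borrows its spread from the other groups. The fit of all 24 columns holds the shared stage 7 libraries under both genotypes, which makes the genotype difference there smaller by construction. DESeq2 called 72 genes, and the fit of all 24 columns called 0.

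At stage 8, when pollen matures, the same identifier OsIR64_07g0000620 was lower in the mutant, at 27.6 ± 6.72 CPM (SD, n = 3) against 112 ± 23.7 CPM (SD, n = 3) in wild type. Its log2 fold change was -2.03 (SE 0.21, edgeR adjusted p = 4.7e-04). OsIR64_05g0013870 was higher in the mutant, at 10.1 ± 3.82 CPM (SD, n = 3) against 1.23 ± 0.608 CPM (SD, n = 3), a log2 fold change of 3.04 (SE 0.42, edgeR adjusted p = 0.014). These were the 2 genes called, while 3564 genes had an unadjusted p under 0.05. Without mutant replicate 3 the count was 2008 genes, 849 higher and 1159 lower. It was 5 without mutant replicate 2 and 1 without wild-type replicate 3. OsIR64_05g0013870 lost its call without wild-type replicate 1 (edgeR adjusted p = 0.13) and without wild-type replicate 3 (edgeR adjusted p = 0.081). DESeq2 called 532 genes, both named genes among them, and the 6 stage 8 libraries alone gave 0. The fit of all 24 columns called 133 genes, of which 1 was shared with the 2 above. OsIR64_07g0000620 was not called there (log2 fold change -2.04, edgeR adjusted p = 0.061). Libraries that stand under both genotypes enter the spread of that fit in both.

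The test of whether the genotype difference changed with stage called 0 genes in edgeR, with 1309 genes at an unadjusted p under 0.05. The DESeq2 likelihood ratio test called 56 genes. Without mutant stage 8 replicate 3, edgeR called 116 genes. Differences between stages in the number of genes called are therefore not shown to be differences in effect by this test.

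Averaged over the 4 stages, 14 genes differed between the genotypes, 5 higher and 9 lower in the mutant. OsIR64_02g0016870 was higher in the mutant, at 20.7 ± 12.9 CPM (SD over 9 libraries of all stages) against 0.361 ± 0.488 CPM (n = 9), with an edgeR adjusted p = 0.0035. Wild type had 3, 1 and 1 counts in all at stages 5, 6 and 7, so its fitted fold change is imprecise, and it lost its call with all 24 columns (edgeR adjusted p = 0.22). OsIR64_05g0013870 was higher by 2.65 on the log2 scale (SE 0.27, edgeR adjusted p = 2.9e-04). OsIR64_05g0008480 was lower, at 1.11 ± 1.11 CPM against 8.19 ± 2.22 CPM (SD, n = 9 each), a ratio of means of 7.39, with an edgeR adjusted p = 2.9e-04. The mutant stage 7 library had a count of 0 for OsIR64_05g0008480, so the fitted mean over 4 stages is not given. Over stages 5 and 8, where every group had counts, the log2 fold change was -2.71, and the call was lost with all 24 columns (edgeR adjusted p = 0.06). OsIR64_10g0005940 was lower, at 14.8 ± 6.02 CPM against 52.0 ± 17.7 CPM (SD, n = 9 each), with a log2 fold change of -2.05 (SE 0.25, edgeR adjusted p = 0.0027), and was not called with all 24 columns (edgeR adjusted p = 0.081). All 14 genes had the same sign at each of the 4 stages, and 7 of them separated the 9 mutant from the 9 wild-type libraries without overlap. The fit of all 24 columns holds the shared libraries under both genotypes, which shrinks the differences at stages 6 and 7 by construction. Calls lost in that fit are therefore a weak check. The averaged contrast was chosen after the data were examined. DESeq2 gave 371 genes, and edgeR gave 484 without mutant stage 8 replicate 3, 53 without wild-type stage 6 replicate 1, 28 without wild-type stage 5 replicate 1, 9 without mutant stage 5 replicate 3 or mutant stage 6 replicate 1, and 8 without mutant stage 6 replicate 2. Without mutant or wild-type stage 8 replicate 1 it gave 15, with 8 higher and 7 lower, so the excess of lower genes turned.

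**Figure D2:**
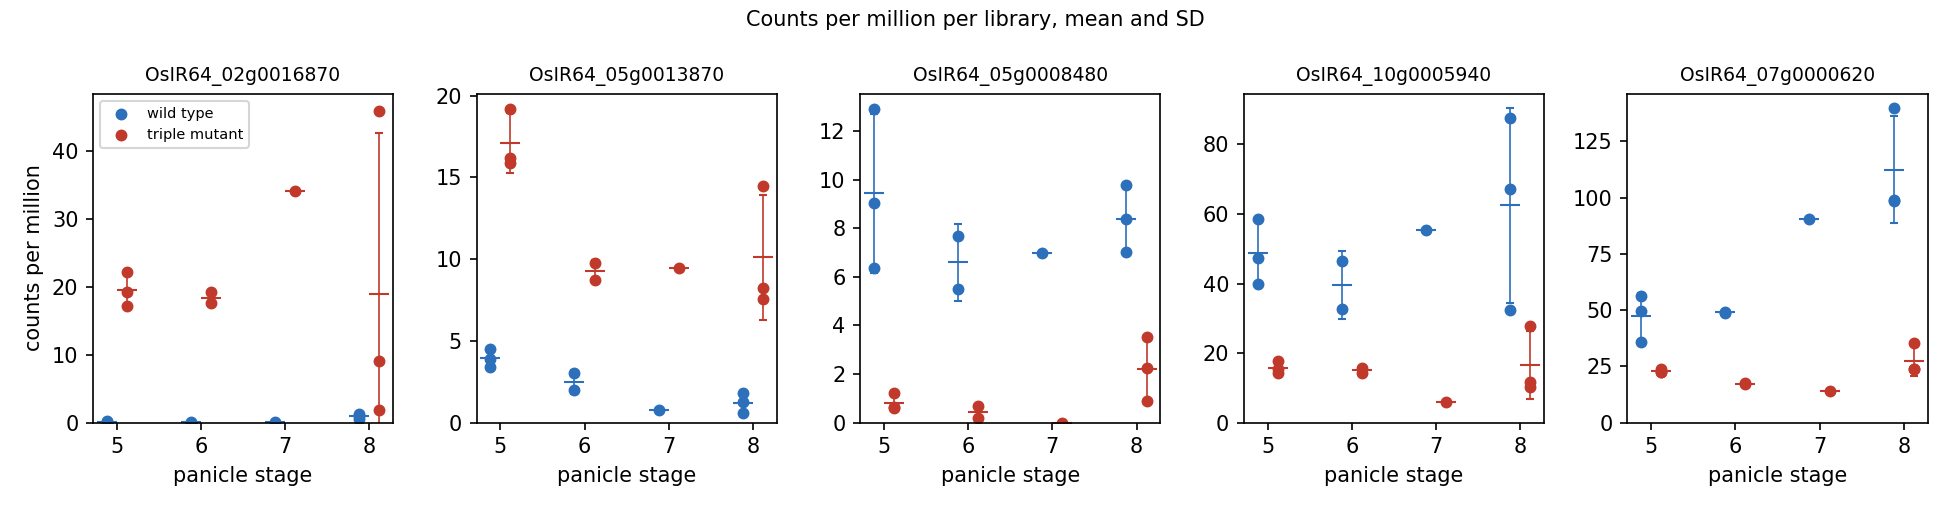
CPM per library (points) with mean and SD (bars, where there were at least 2 libraries) against panicle stage for 5 genes, wild type in blue and mutant in red. OsIR64_07g0000620 in wild type had a mean of 47.2 CPM at stage 5 and 112 CPM at stage 8, against 23 and 27.6 CPM in the mutant.

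From stage 5 to stage 6, more genes rose than fell in both genotypes. In wild type 818 genes changed, 723 higher and 95 lower, and in the mutant 1733 changed, 1319 higher and 414 lower. OsIR64_07g0026440 had no count at stage 5 in either genotype. At stage 6 it reached 110 ± 28.7 CPM (SD, n = 2) in wild type and 129 ± 42.9 CPM (SD, n = 2) in the mutant. Against a floor of 3 counts over the group these means were at least 1310-fold and 1520-fold higher. The lower library of each genotype was at least 1100-fold and 1200-fold higher. OsIR64_04g0024450 fell in both, from 7.72 ± 0.994 CPM (SD, n = 3) to 0.476 ± 0.449 CPM (SD, n = 2) in wild type. Its wild-type call (log2 fold change -3.99, edgeR adjusted p = 0.028) was lost in 4 of 5 fits that left out 1 library, with adjusted p from 0.058 to 0.26, and kept only without replicate 1 of stage 6 (0.04). Of the genes that rose, 623 were called in both genotypes, against 37.4 for independent lists, and of those that fell 66, against 1.5. Here and for the later steps both lists came from the same fit and stages. An overlap above this reference therefore does not measure how alike the genotypes are. Across all genes the log2 fold changes of the genotypes correlated at 0.561 for this step, 0.418 for the next and 0.496 for the last. The wild-type count was 240 without replicate 2 of stage 6, 368 without replicate 1 of stage 5 and 540 without replicate 3 of stage 5. The genes that fell numbered 6, 18 and 62 in these fits, and 50 without replicate 2 of stage 5. The mutant count was 549 and 591 without replicates 2 and 1 of stage 6, and 691 and 699 without replicates 2 and 3 of stage 5, with 38, 37, 93 and 94 genes that fell. Leaving out replicate 1 of stage 5 gave 255 that fell. Fitted alone, the libraries of the step gave 423 genes in wild type, 373 higher and 50 lower, and 7671 in the mutant, 4127 higher and 3544 lower.

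From stage 6 to stage 7, 2579 genes changed in wild type, 1491 higher and 1088 lower, and 744 in the mutant, 639 higher and 105 lower. OsIR64_01g0044260 had no count at stage 6 in either genotype and stood at 568 CPM in the wild-type and 205 CPM in the mutant stage 7 library. Among falling genes, OsIR64_04g0016450 went from 6.83 ± 3.14 CPM (SD, n = 2) to 0 in wild type. This was at least 26-fold lower by the group mean and 18-fold by the lower library. In the mutant, OsIR64_12g0018400 went from 5.41 ± 1.7 CPM (SD, n = 2) to 0. This was at least 21.4-fold lower by the group mean and 17-fold by the lower library. At stage 8 the mutant again had 6.72 ± 1.58 CPM (SD, n = 3), so this fall rests on a count of 0 in 1 library. Of the genes that rose, 574 were called in both genotypes, against 37.4 for independent lists, and 35 of those that fell, against 4.5. Stage 7 had 1 library per genotype, and the mutant count was 199 and 298 without replicates 1 and 2 of stage 6, with 11 and 26 genes that fell. The wild-type count was 1057 without replicate 1 of stage 6, with 363 that fell. OsIR64_12g0018400 was not called with all 24 columns (edgeR adjusted p = 0.083). When only the 3 libraries of each step were fitted, the order of the genotypes turned, with 482 genes in wild type, 450 higher and 32 lower, and 6301 in the mutant, 3585 higher and 2716 lower. Which genotype had the more even split of directions thus turned as well. Those fits had 1 residual degree of freedom, so their spread came from the 2 stage 6 libraries alone. The turn therefore does not show which order holds.

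From stage 7 to stage 8 the fit of 18 libraries called 61 genes in wild type, 1 higher and 60 lower, and 2723 in the mutant, 1085 higher and 1638 lower. OsIR64_11g0001060 fell in wild type from 102 CPM to 11.1 ± 4.06 CPM (SD, n = 3), and OsIR64_09g0001710 rose from 30 CPM to 67.2 ± 3.94 CPM (SD, n = 3). OsIR64_11g0001060 (edgeR adjusted p = 0.046) lost its call without replicate 1, 2 or 3 of stage 8 (0.16, 0.065 and 0.13), and OsIR64_09g0001710 (edgeR adjusted p = 0.033) without replicate 1 or 3 (0.12 and 0.074). In the mutant OsIR64_04g0007750 rose from no count to 170, 346 and 9.59 CPM in replicates 1, 2 and 3, at least 38-fold in the lowest, and OsIR64_06g0011870 fell from 8.18 CPM to 0.107 ± 0.185 CPM (SD, n = 3). Of the 60 genes that fell in wild type, 57 were also called lower in the mutant, against 3.9 for independent lists. The wild-type count was 1 without replicate 1 of stage 8, 10 without replicate 3 and 4094 with all 24 columns. The mutant count was 4275 without replicate 3 of stage 8. DESeq2 called 4139 genes in the mutant, 2248 higher and 1891 lower, so the excess of falling genes turned, and 480 in wild type, 209 higher and 271 lower. When only the 4 libraries of each step were fitted, the order of the genotypes turned, with 554 genes in wild type, 266 higher and 288 lower, and 0 in the mutant.

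**Figure D3:**
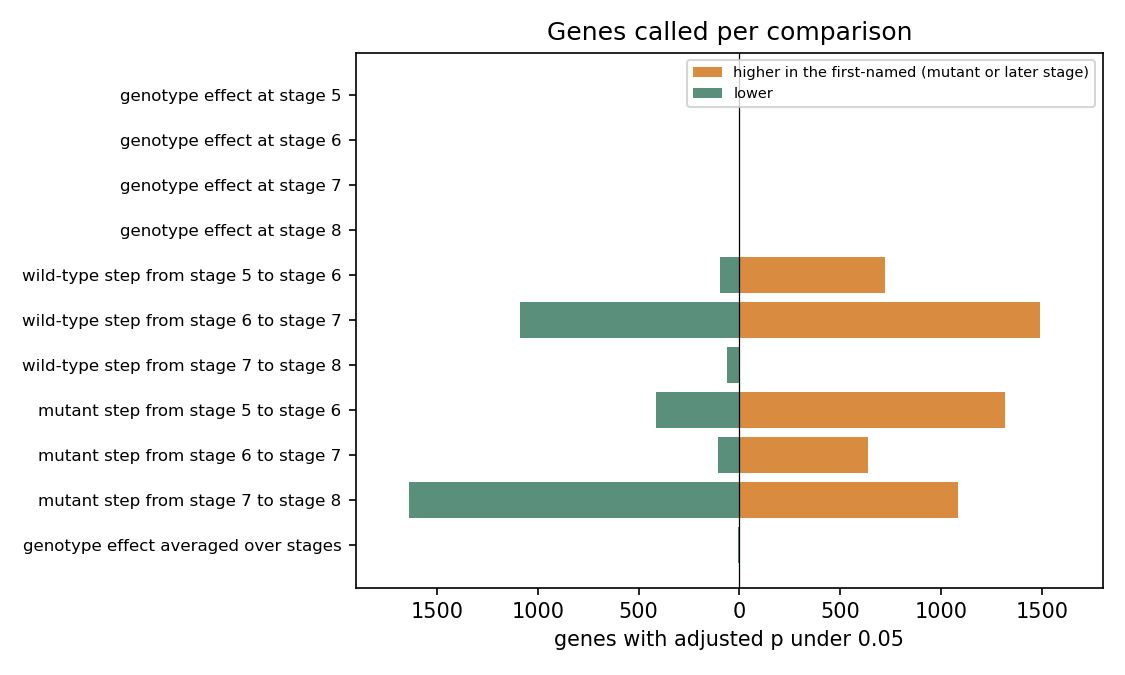
Number of genes with an edgeR adjusted p under 0.05 per comparison, higher to the right and lower to the left. The genotype comparisons at single stages called at most 2 genes, and the steps between stages 61 to 2723.

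The stage 8 mutant libraries lay on both sides of the wild-type ones on the axis from the stage 6 mean (0%) to the stage 8 mean (100%). Mutant replicates 1, 2 and 3 stood at 110.4%, 107.8% and 85.5%, and the wild-type replicates at 101.5%, 96.7% and 97.7%.

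**Figure D4:**
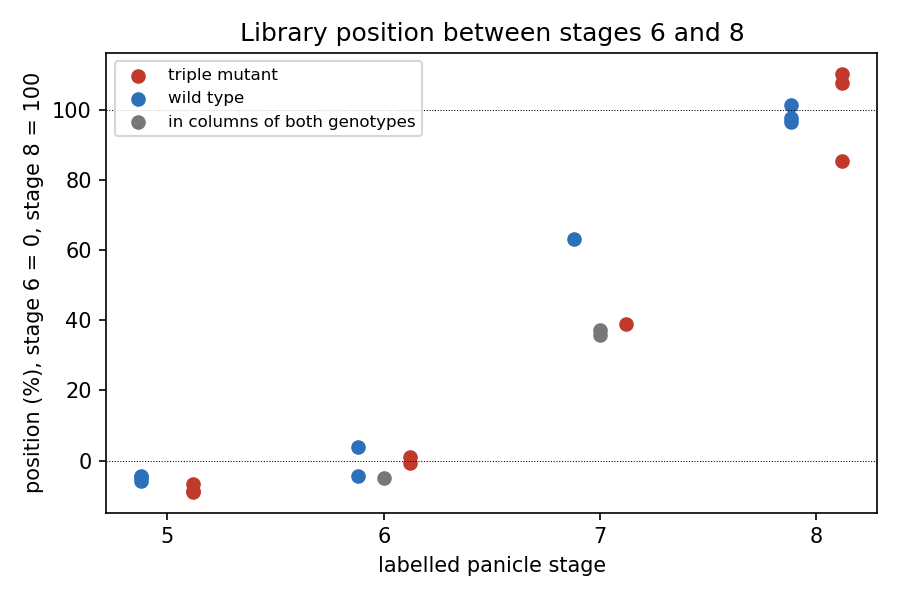
Position of each of the 21 distinct libraries between the stage 6 mean (0%) and the stage 8 mean (100%), against the labelled panicle stage. At stage 7 the wild-type library stood at 63.2% and the mutant library at 38.9%.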

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

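The tests of the shared libraries and of the position of the stage 7 libraries were chosen after the results were seen, while the tests of depth, of developmental progress and of other splits of the libraries were written before their results were seen.

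The 3 libraries that stood under both genotypes were used in no comparison. In a few genes that differ between the genotypes they lay mostly nearer the mutant. A fit of the stage 5 and stage 8 libraries alone gave 7 such genes, and the shared libraries lay nearer the mutant than the wild-type library or libraries of their own stage for 7 genes (stage 6 replicate 3), 6 genes (stage 7 replicate 2) and 6 genes (stage 7 replicate 3), so at least 85.7% of genes and at most 100%. That measure replaced a first one, distance to means pooled over stages 5 and 8, which gave 57.1% to 100%. The first one put 8 of 18 libraries of known genotype outside the bound set for a control and so decided nothing. Some of these still lay nearer their own genotype, as the mutant stage 7 library did for 57.1% of genes. With the second measure both mutant stage 6 libraries lay on the mutant side for 7 genes. Yet 1 wild-type stage 6 library still did so for 2 genes, above the bound set for a control. At stage 7 there was no such control, since each genotype had 1 library. Across genes the shared stage 7 libraries correlated at 0.952 and 0.956 with the mutant library, and at 0.951 and 0.952 with the wild-type one. The shared stage 6 library correlated at 0.968 and 0.966 with the mutant libraries, and at 0.968 and 0.952 with the wild-type ones. Mutant libraries entered under wild-type names may account for the values of the 7 genes. Neither direction of mislabelling is settled by 7 genes, and the libraries were not assigned to a genotype.

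In the fit of 18 libraries the steps around stage 7 differed in number of calls between the genotypes in opposite ways. Both orders turned when only the libraries of each step were fitted, so the pattern depends on which libraries enter the fit. Those fits had 1 residual degree of freedom for the step from stage 6 and 2 for the step from stage 7. Their spread came from few replicates, so they do not settle either order. In the fit of 18 libraries, with every library thinned to the same total the smaller of the 2 ratios between genotypes was still 3.51, which argues against depth there. On the axis from stage 6 (0%) to stage 8 (100%) the wild-type stage 7 library lay at 63.2% and the mutant one at 38.9%, a gap of 24.3 points against ranges of 8.4 points among the stage 6 libraries and 24.9 points among the mutant stage 8 libraries. The 2 shared stage 7 libraries lay at 35.9% and 37.2%. The mutant mean was ahead by 0.4 points at stage 6 and 2.6 points at stage 8, less than the replicate ranges. Stage 5 is outside the span of the axis. There the mutant libraries (-6.8%, -8.6% and -8.9%) all had lower values than the wild-type ones (-4.6%, -4.5% and -5.9%). Wild-type stage 6 replicate 1 (-4.4%) and the shared stage 6 library (-5.1%) stood level with wild-type stage 5. Values at stage 5 therefore do not show which genotype was behind. The gap passed the bound written for this test, the range of the stage 6 libraries, but not the range of the mutant stage 8 libraries. Ranges within the other groups of replicates were 1.4 to 8.4 points. With 1 library per genotype, a delay of the mutant, a different harvest time and replicate spread cannot be told apart. The gap is also no wider than the widest replicate range.

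The 14 genes of the averaged contrast stood out from chance groupings of the same libraries. Among 100 splits drawn within stages, 1 gave as many genes, the real one, and the highest other split gave 0. With equal totals 13 of the 14 stayed past the threshold, which argues against depth. For 8 of the 14 the genotype difference exceeded the largest change between adjacent stages. This share is too near even to exclude a difference in developmental progress for the whole list. The log2 difference was -1.82 against 0.62 for OsIR64_07g0000620, and 2.65 against 0.77 for OsIR64_05g0013870. It was -2.05 against 0.7 for OsIR64_10g0005940 and 1.16 against 0.16 for OsIR64_01g0011200. For these genes the values argue against a lag of up to 1 stage. Others, such as OsIR64_10g0006810 (-1.3 against 2.62), leave it open. An effect of the edited genes remains a hypothesis, and changes linked to the edited lines by descent were not tested.

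For the genotype comparisons at single stages the 10 splits of 6 libraries are too few for a share under 0.05. At stage 5 the real split gave 0 genes and the highest other 0, so all 10 gave as many. At stage 8 the real split gave 2 genes and the highest other 51, and 4 of 10 gave as many. The split with 51 genes set mutant replicates 1 and 3 and wild-type replicate 3 against the others. What sets these libraries apart was not tested. Along genotype, leaving out mutant replicate 3 gave 2008 genes.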

How the results depend on the processing

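The fit of all 24 columns was the planned one and became an alternative after the shared columns were seen. Every fit of the averaged contrast was chosen after seeing the data. RLE size factors, no low-count filter and the 2-fold minimum left every total count within 1.5 times, but the 2-fold minimum cut the genes that fell from stage 5 to stage 6 from 95 to 43 in wild type and from 414 to 199 in the mutant. DESeq2 gave 16, 6, 72 and 532 genes for the genotype at stages 5, 6, 7 and 8, 1629 and 480 for the wild-type steps from stages 5 and 7, 2743, 1468 and 4139 for the mutant steps, 56 for the interaction and 371 for the averaged contrast. Fitting only the libraries compared gave 7 genes at stage 5 and 0 at stage 8, 423, 482 and 554 for the wild-type and 7671, 6301 and 0 for the mutant steps; at stage 7 such a fit has no residual degrees of freedom and was not made. All 24 columns gave 0 genes at stage 7 and 133 at stage 8, 1736, 5571 and 4094 for the wild-type and 3040, 3934 and 7850 for the mutant steps, and 5 for the averaged contrast. The common biological coefficient of variation was 34.1% over the 18 libraries, against 18.5% at stage 5 and 41.4% at stage 8. The shared spread was thus wider than that of stage 5 and narrower than that of stage 8. How much of these shifts this accounts for was not tested.

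Same-numbered mutant and wild-type libraries of a stage correlated in their deviations at 0.012 to 0.061. At stages 5 and 8, 3 of 12 correlated best with their own number, so this check gave no clear sign of a pairing. Whether the numbers pair libraries across stages, as the block for the steps assumes, was not checked. With the replicate block the counts were 171 for the wild-type step from stage 7, 481 for the mutant step from stage 6 and 9 for the averaged contrast. Other total counts stayed within 1.5 times, which does not cover the split into higher and lower genes.

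Leaving out 1 library gave 0 to 11 genes for the genotype at stage 5, 1 to 2008 at stage 8, 240 to 895, 1057 to 2882 and 1 to 61 for the wild-type steps, 549 to 1190, 199 to 298 and 2311 to 4275 for the mutant steps, 0 to 116 for the interaction and 8 to 484 for the averaged contrast. Stage 6 stayed at 0. Leaving out a stage 7 library gives no value for its group. Where 1 library was left in a group it was assumed to vary like the others. Among values of named genes under the alternatives, 303 kept their direction and side of the threshold, 59 kept the direction and lost the call, and none reversed. The 2-fold minimum gave 30 of the 303 and could not change them, since it reuses the main fit. The named genes were also chosen for large changes without overlap in these data.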

Other observations

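The tests in this part were chosen after the data were seen, on classes of genes made from the same libraries.

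Genes were grouped by the stage at which their mean over both genotypes was at least 2-fold above every other stage, which gave 691 genes for stage 5, 198 for stage 6, 880 for stage 7 and 2464 for stage 8. At stage 8, 669 of the 880 stage 7 genes (76%) had lower fitted values in the mutant, with a median log2 difference of -0.84, and 0 were called singly. Camera of limma gave an adjusted p = 2.2e-13 with its preset correlation and an adjusted p = 0.74 with an estimated correlation, and fry gave an adjusted p = 0.17, over 16 tests. The difference was uneven among the mutant libraries. The class median was -3.64 log2 CPM in mutant replicate 2, the value of a gene with no count. It was -0.06 and 0.52 in replicates 1 and 3, and 0.35, 0.85 and 0.57 in the wild-type libraries. The stage 8 libraries helped set the classes, so a low mean there favoured entry into the stage 7 class. Mutant replicates at stage 8 varied more than wild-type ones, so the direction was not independent of the selection. At stage 8 the stage 8 class went the other way, with a median log2 difference of 0.48. Of its 2464 genes, 789 (32%) were lower in the mutant.

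At stage 7, 1525 of the 2464 stage 8 genes (61.9%) had lower fitted values in the mutant library than in the wild-type library, with a median log2 difference of -0.74. The adjusted p was 4.0e-10 with the preset and 0.74 with an estimated correlation (camera of limma). The class median was -2.61 log2 CPM in the mutant and -0.54 in the wild-type stage 7 library, and -1.29 and -1.14 in the shared ones. At stage 7 the stage 5 class went the other way, with 139 of 691 genes (20.1%) lower in the mutant. No class test in the 4 genotype comparisons passed with an estimated correlation.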
